A study of Arabidopsis thaliana with 18 samples.

How the data were processed

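RNA from leaves of Arabidopsis thaliana was measured by sequencing in 18 samples. Per the labels, plants were 4 weeks old, grew in 8 h of light and 16 h of dark, and were sprayed with 50 µM dexamethasone, and each sample was 0.4 g of the 4th leaf pooled from 4 plants. Libraries were made with a stranded mRNA kit. There were 2 lines (NAA50 amiRNA and scrambled amiRNA), 3 times (0, 12 and 24 h) and 3 samples per line and time, and no sample stood in more than 1 group. The labels give no pairing of samples across groups, and the sample numbers were checked through the correlations of deviations from the group means between samples of the same number. These ran from -0.485 to 0.409, and 21 of 45 were above 0.1. All 3 were above 0.1 between the lines at 12 h (0.128, 0.220 and 0.342) and between the scrambled line at 0 h and the NAA50 line at 24 h (0.102, 0.284 and 0.103), but not in the other 13 pairs of groups. The main fit, fixed before the data were examined, treats samples as unpaired, and a fit with the number as a block was run as an alternative.

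The table deposited by the authors holds raw counts per gene, per the labels and its values (whole numbers, column totals that differ between samples). It has 23790 genes and 18 sample columns, all used. The submitters' notes name Trimmomatic, STAR, DESeq2 and the build TAIR10, without versions or roles, and the counting program, its strand setting and the annotation are not given in the sources used here. Columns were matched to samples by line, time and number. For the scrambled samples at 12 h the short code in the sample titles differs from the column name, and the time stated in the title was used. Gene symbols and positions came from a copy of the TAIR10.1 annotation, in which 23500 of the gene identifiers (98.8%) were found. Genes are named by their symbol there, or by their locus identifier where it gives none.

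Libraries held 10389333 to 12353330 counts. A count of 0 in a library allows a level of up to 0.243 to 0.289 CPM (3 counts). Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 18344 genes (77.1%). Libraries were scaled by TMM, 1 mean per group was fitted to all 18 libraries, and contrasts were tested with the quasi-likelihood F test (12 residual degrees of freedom, biological coefficient of variation 18.16%, prior count 0.125). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The contrasts were the line difference at 0, 12 and 24 h (NAA50 line minus scrambled line), the knockdown response at 12 and 24 h (the line difference minus that at 0 h) and the line difference at 24 h minus that at 12 h. Others were the changes from 0 to 12 h and from 0 to 24 h in each line. The SE of a log2 change is its size divided by the square root of its F value. Principal components were computed from log2 CPM with a prior count of 2.

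Before the data were examined, 21 lists of genes were fixed: salicylic acid and systemic immunity, pattern-triggered immunity, camalexin and indole metabolism, jasmonate, ethylene, abscisic acid and drought, auxin, senescence, cell wall loosening, cell division, circadian clock, photosynthesis, cytosolic ribosome, ER stress and protein folding, heat shock and cytosolic protein folding, oxidative stress and detoxification, N-terminal acetyltransferase subunits, and markers of guard cells, phloem and bundle, xylem, and epidermis and trichomes. Of their members 12 were left out, 8 because the annotation gives another symbol at the locus and 4 because it gives the symbol to another locus. Among the 8 were the acetyltransferase subunits NAA15, NAA30 and NAA35, whose genes were measured and passed the filter. Of the 419 kept, 393 were tested. Lists were tested with camera (limma 3.58.1, on log2 CPM) at a preset correlation of 0.01, again with an estimated correlation, and with fry, with p-values adjusted over the lists of a comparison. Over the 4 main comparisons camera called 13 of the list results with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.761. Camera compares a list with the other genes, and fry tests whether its members move one way on balance.

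Named genes follow a rule also fixed before the data were examined. It takes NAA50, the 6 largest increases and 6 largest decreases in each main comparison (knockdown response and line difference, each at 12 and 24 h). It also takes the 3 largest each way in the other comparisons, and up to 3 members of each list with the smallest adjusted p in each main comparison. The largest changes were taken among called genes with a mean log2 CPM of 1 or more and no overlap between the 3 and 3 libraries, which chance gives in 10% of genes. TCP, clock, microRNA and organ marker genes given in the closing part were chosen apart from this rule. A gene counts as having a near-identical copy at 95% identity over 50% of its length (BLAST 2.17.0). A fold is a ratio of counts summed over a group and scaled by its summed library sizes, so it can differ from the ratio of the mean CPM. Folds given among the knockdown responses compare the lines at that time, and are not the response, which also subtracts the line difference at 0 h. A fold against a group at 0 counts was computed against 3 counts over the group and is given as a lower bound, and with 1 to 3 counts the ratio is given with its 95% interval.

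The procedure was tested on simulated data built from the same counts, with 200 changed genes drawn among those at a mean of 5 CPM or more. Recovery at lower levels, and false calls where as many genes change as were called in the real data, were not tested. For the line difference at 24 h it called 80% of genes raised 2-fold, 100% of those raised 4-fold, 80% of those lowered to 0.5 and 96% of those lowered to 0.25 of their level, and 4 of 17842 unchanged genes. For the knockdown response at 24 h it called 36%, 96%, 52% and 90% of these, and 8 of 17843 unchanged genes.

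The alternatives were DESeq2 size factors, library size alone, no filter beyond 1 count, the Wald test of DESeq2 1.42.0, a fit of only the groups compared, the sample number as a block, no chloroplast and mitochondrial genes (167 genes), a minimum change of 1 on the log2 scale, a mean log2 CPM of 3 or more for the correlations, and each library left out in turn. Regroupings of the same libraries were counted for each comparison, all 10 for 3 against 3 and 40 drawn of 200 for the others. Sequence searches and drawing used Python 3.11.15 with SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9. Splicing, sequence variants and protein levels were not analysed here.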

Results

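Leaf RNA of Arabidopsis thaliana was sequenced in 18 libraries from 2 transgenic lines in which dexamethasone, a synthetic glucocorticoid, switches on an artificial microRNA (amiRNA). In the NAA50 line the amiRNA is directed at NAA50, which encodes a catalytic N-terminal acetyltransferase subunit, and in the scrambled line, the negative control, its sequence is scrambled. Leaves were taken 0, 12 and 24 h after a spray with 50 µM dexamethasone, and each of the 6 groups held 3 libraries, each from 4 pooled plants. The libraries held 10389333 to 12353330 counts, and 19989 to 20931 genes had at least 1 count. Levels are counts scaled to library size (CPM), given as the mean or as mean ± SD with n = 3 libraries, folds are ratios of summed counts, and changes are log2 values ± SE with adjusted p-values from edgeR.

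The first principal component carried 51.1% of the variance and set the NAA50 line at 12 and 24 h apart from the other 12 libraries. The second carried 18.1% and ran from the 0 h libraries to the scrambled libraries at 12 and 24 h. At 0 h the scrambled library 2 lay apart from the other libraries, at -102.6 on the first and -74.8 on the second component, with a scaling factor of 0.864 and 11.2% of its counts in its 10 most abundant genes. The scaling factors of all libraries ranged from 0.864 to 1.09, and the share of the 10 most abundant genes ranged from 3.70% to 11.2%.

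**Figure D1:**
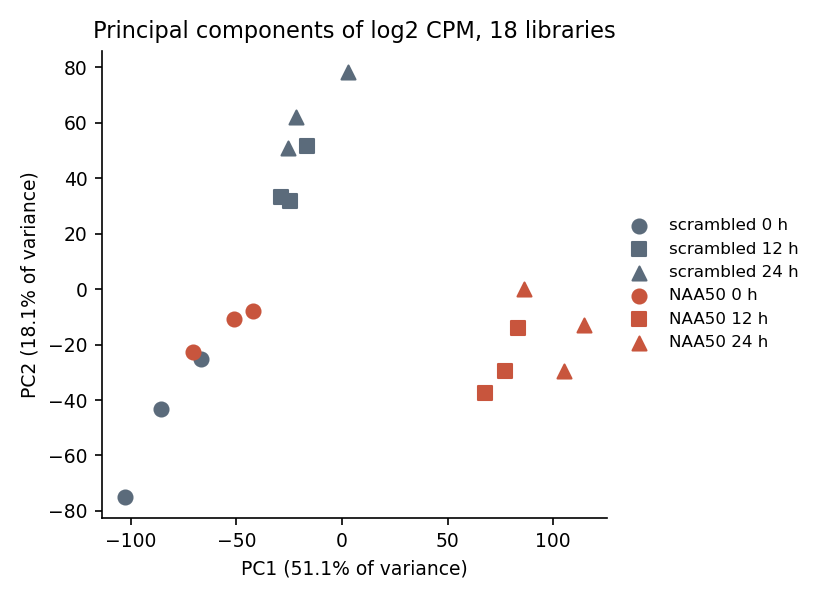
Principal components of log2 CPM, with the first on the x axis (51.1% of the variance) and the second on the y axis (18.1%). Each point is 1 of 18 libraries, coloured by line and shaped by time, and the 6 NAA50 libraries at 12 and 24 h lie to the right of the 12 others.

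NAA50 (AT5G11340, chromosome 5, 3619152 to 3621511 on the plus strand of TAIR10.1, a protein-coding gene) fell in the NAA50 line after dexamethasone. Its level in that line was 12.6 ± 0.932 CPM at 0 h, 3.68 ± 0.522 at 12 h and 3.43 ± 1.14 at 24 h (n = 3). In the scrambled line it was 14.0 ± 0.705, 15.0 ± 1.99 and 16.9 ± 0.832 CPM. The difference between the lines did not pass the test at 0 h (-0.16 ± 0.16, adjusted p = 0.664), was -2.03 ± 0.18 at 12 h (adjusted p = 5.38e-07, 24.5% remaining) and -2.28 ± 0.18 at 24 h (adjusted p = 1.47e-07, 20.6% remaining). Each of the 6 NAA50 libraries at 12 and 24 h lay below each of the other 12. The change of NAA50 from 0 h in its own line was -1.77 at 12 h (adjusted p = 1.12e-06) and -1.85 at 24 h (adjusted p = 7.75e-07), against 0.10 (adjusted p = 0.650) and 0.27 (adjusted p = 0.168) in the scrambled line. The difference between the lines at 24 h minus that at 12 h did not pass (-0.25 ± 0.25, adjusted p = 0.578). The gene shares 58 bp with AT5G11350 on the same strand.

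**Figure D2:**
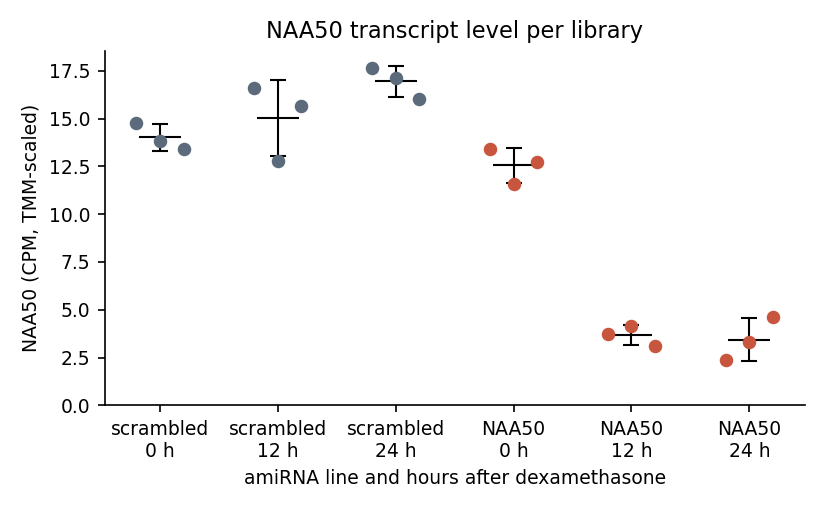
NAA50 in CPM on the y axis by line and hours after dexamethasone on the x axis, with 1 point per library and bars for the mean ± SD of 3 libraries. The NAA50 line fell from 12.6 CPM at 0 h to 3.68 at 12 h and 3.43 at 24 h, while the scrambled line lay between 14.0 and 16.9.

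Whether the lines differed before the amiRNA was induced is the question at 0 h. MAF5, of the family of MADS-box floral repressors, was higher in the NAA50 line (7.89 ± 1.73 against 0.602 ± 0.417 CPM, 13.8-fold), and PGIP2, an inhibitor of fungal polygalacturonases, was lower (8.12 ± 1.77 against 41.2 ± 16.5 CPM, 5.03-fold). AT2G44240 (change 4.63 ± 0.74) and AT4G12500 (4.51 ± 0.73) were higher as well, and AT5G06865 was lower (-2.40 ± 0.35), with 79.9% of its length overlapped by its neighbour PGIP1. In all 18 genes passed, 16 higher and 2 lower, and 2434 had an unadjusted p under 0.05. DESeq2 called 308 genes (282 higher), edgeR 36 with the sample number as a block, 32 without a filter and 0 when fitted to only these 2 groups (1708 at an unadjusted p under 0.05). The count was 4, 3 and 354 without scrambled 0 h library 1, 2 and 3, and 5, 73 and 3 without NAA50 0 h library 1, 2 and 3. The calls of AT2G44240 and AT4G12500 ended without scrambled 0 h library 1 (adjusted p = 0.225) or 2 (0.197) or NAA50 0 h library 3 (0.0778), and that of AT4G12500 also without NAA50 0 h library 1 (0.0689). That of AT5G06865 ended without scrambled 0 h library 2 (0.119) or NAA50 0 h library 1 (0.0689) or 3 (0.0778).

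Several gene lists were shifted at 0 h by camera, a competitive test of a list against the other genes. The abscisic acid and drought list was higher (median 1.24, adjusted p = 1.04e-06), as were the camalexin and indole metabolism list (0.62, adjusted p = 1.10e-07), the jasmonate list (0.73, adjusted p = 3.93e-05) and the senescence list (0.35, adjusted p = 5.54e-07). In NAA50 0 h libraries 1, 2 and 3 COR47 was at 174, 92.5 and 614 CPM, ERD10 at 135, 71.7 and 460 and HAI1 at 10.7, 0.955 and 108, against 101 to 137, 79.2 to 126 and 0.107 to 2.07 in the scrambled libraries. Without NAA50 0 h library 3 the abscisic acid and drought median was 0.39 (adjusted p = 0.0489). The photosynthesis list (-0.42, adjusted p = 1.24e-12) and the cell division list (-0.35, adjusted p = 0.00234) were lower. No call at 0 h held with an estimated correlation (adjusted p = 0.415 for these 6 lists). Over all genes tested by edgeR 0 members of these 6 lists passed at 0 h. At an unadjusted p under 0.05 they were 18 abscisic acid, 10 camalexin, 5 jasmonate and 8 senescence genes, all higher, and 6 photosynthesis and 2 cell division genes, all lower. DESeq2 called 9 abscisic acid, 1 camalexin, 1 jasmonate and 4 senescence members, all higher, and 0 photosynthesis and 0 cell division members. Adjusted over the list alone 16 abscisic acid, 10 camalexin and 8 senescence members were higher. Without scrambled 0 h library 3 the members passing over all genes were 3 abscisic acid, 4 camalexin, 5 jasmonate and 4 senescence genes, all higher, and without NAA50 0 h library 2 they were 4 abscisic acid genes and 1 senescence gene. The medians without scrambled 0 h library 3 were 1.38 for abscisic acid, 0.86 for camalexin, 1.65 for jasmonate and 0.55 for senescence.

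The salicylic acid and systemic immunity list (median 0.47, adjusted p = 1.98e-07) and the oxidative stress and detoxification list (0.63, adjusted p = 4.01e-06) were higher at 0 h too (adjusted p = 0.415 for both with an estimated correlation), and a difference at 0 h is subtracted in the knockdown response. Of 27 salicylic acid members 0 passed in edgeR, 0 in DESeq2 and 0 adjusted over the list alone, with 4 at an unadjusted p under 0.05. The salicylic acid call ended without scrambled 0 h library 2 (0.13, adjusted p = 0.0614). Without scrambled 0 h library 3 its median was 1.01 and 4 members were higher. Of 22 oxidative stress members 1 was higher in edgeR and 3 in DESeq2 (4 adjusted over the list alone). That count was 4 without scrambled 0 h library 3, 2 without NAA50 0 h library 2, and 0 without scrambled 0 h library 1 or 2 or NAA50 0 h library 1 or 3. The ethylene (0.90, adjusted p = 0.0168), pattern-triggered immunity (0.27, adjusted p = 0.00798) and ER stress (0.16, adjusted p = 0.00798) lists were called as higher and the auxin (-0.45, adjusted p = 0.0331) and cell wall loosening (-0.50, adjusted p = 0.0159) lists as lower. With an estimated correlation the adjusted p was 0.415 for ethylene and auxin, 0.445 for pattern-triggered immunity and cell wall loosening and 0.698 for ER stress. The ethylene and pattern-triggered immunity calls ended without scrambled 0 h library 1 (0.177 and 0.357) or NAA50 0 h library 1 (0.211 and 0.346) and with library-size scaling (0.116 and 0.0503). The pattern-triggered immunity median was 0.07 without NAA50 0 h library 1 and 0.60 without scrambled 0 h library 3. The ER stress and cell wall loosening calls ended without scrambled 0 h library 2 (0.0673 and 0.113) or NAA50 0 h library 3 (0.0858 and 0.0671), and the auxin call without scrambled 0 h library 2 (0.131) or NAA50 0 h library 1 (0.0523). The ER stress median changed sign, to -0.18 without scrambled 0 h library 2 and -2.64e-04 without NAA50 0 h library 3.

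The knockdown response asks which genes changed after dexamethasone in the NAA50 line beyond their change in the scrambled line. It is the change from 0 h in the NAA50 line minus that in the scrambled line, so a negative response can come from a fall in the NAA50 line, a rise in the scrambled line, or both. At 12 h NAA50 had a response of -1.87 ± 0.24 (adjusted p = 8.25e-05). The strongest positive responses came from genes barely detected in the other groups. CYS2, a cysteine protease inhibitor, was at 1319 ± 71.0 CPM in the NAA50 line at 12 h against 0.759 ± 0.452 in the scrambled line (1768-fold) and 3.27 ± 2.46 at 0 h. PIRL8, a leucine-rich repeat protein, reached 144 ± 7.94 against 0.187 ± 0.0918 CPM (770.3-fold), and PME5, a pectin methylesterase, 87.0 ± 28.6 against 0.257 ± 0.302 (351-fold). PEI1, a zinc finger protein known from embryos, was at 33.2 CPM in the NAA50 line and at 0 in all 3 scrambled libraries at 12 h, at least 356-fold higher. LYK2, a LysM receptor-like kinase gene overlapped over its whole length by AT3G01830 on the opposite strand, was 90.8-fold higher than in the scrambled line at 12 h. AT3G10590 was 81.5-fold higher than there.

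Negative responses at 12 h included HMA2, a zinc-exporting ATPase, at 0.236 ± 0.133 CPM in the NAA50 line against 31.3 ± 3.20 in the scrambled line (131-fold), and UMAMIT17, of an amino acid transporter family, at 0.346 ± 0.0969 against 23.7 ± 6.64 CPM (69.2-fold). AT5G05250 was at 1.28 ± 0.731 against 78.3 ± 14.8 CPM (response -6.54 ± 0.70), and it rose in the scrambled line from 6.35 ± 2.60 CPM at 0 h. AT1G14250 had a response of -7.33 ± 1.78, and AT2G44240 one of -6.90 (adjusted p = 4.28e-04), with 21.7 ± 14.7 CPM at 0 h in the NAA50 line. PDF1.2, a plant defensin, had a response of -6.32 ± 2.17 (adjusted p = 0.0434). The PDF1.2 call ended (adjusted p from 0.0551 to 0.164, responses from -6.43 to -5.45) without any 1 of the 3 scrambled 0 h libraries, the 3 scrambled 12 h libraries, NAA50 0 h libraries 1 and 2 and NAA50 12 h libraries 1 and 2.

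The salicylic acid and systemic immunity list had a lower response at 12 h, with 8 of 27 members lower (8 lower adjusted over the list alone), a median of -1.24 and an adjusted p of 3.68e-04 by camera (adjusted p = 0.761 with an estimated correlation, as for each list called here). ALD1, needed for pipecolic acid synthesis, was at 6.69 ± 0.689 CPM in the NAA50 line against 53.0 ± 25.0 in the scrambled line (response -3.40 ± 0.93). GRX480, a glutaredoxin, was at 18.6 ± 6.88 against 60.5 ± 16.6 CPM (response -2.99 ± 0.72). FMO1, which makes N-hydroxypipecolic acid, had a response of -3.69 ± 1.02, and of -5.59 without scrambled 0 h library 3. Without that library 17 members were lower, without scrambled 12 h library 3 there were 4, and without scrambled 0 h library 1 or 2, scrambled 12 h library 2, NAA50 0 h library 3 or NAA50 12 h library 1 or 2 there were 5.

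The oxidative stress and detoxification list was lower as well (5 of 22 members, 7 adjusted over the list alone, median -1.07, adjusted p = 0.00613). GSTU10, a glutathione transferase, had a response of -3.62 ± 0.60 and OPR1, an oxophytodienoate reductase, one of -1.21 ± 0.26. Its count was 8 without scrambled 0 h library 3 or NAA50 12 h library 3, and 3 without NAA50 0 h library 3. In the camalexin and indole metabolism list 5 of 16 members were lower (5 adjusted over the list alone, median -0.91, adjusted p = 0.0110). They included CYP79B3, which makes indole-3-acetaldoxime (5.03 ± 1.28 against 46.0 ± 7.66 CPM, response -3.52 ± 0.61), GGP1 (-1.22 ± 0.24) and MYB34, a regulator of indole glucosinolates (-2.08 ± 0.42). That count was 8 without scrambled 0 h library 3, and the call of the camalexin list ended without NAA50 12 h library 2 (4 members, adjusted p = 0.0664).

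The photosynthesis list had a median of -0.57 at 12 h (3 of 41 members lower, 1 adjusted over the list alone, adjusted p = 3.68e-04). RBCS2B, a small subunit of Rubisco whose reads cannot be fully told from those of the near-identical RBCS3B, had a response of -1.81 ± 0.39. The photosynthesis count was 8 without scrambled 0 h library 2, and 1 without scrambled 0 h library 1 or 3, scrambled 12 h library 1 or 2, NAA50 0 h library 1 or 2, or NAA50 12 h library 1 or 3. The cytosolic ribosome list had a median of -0.37 (2 of 25 members lower in edgeR and 3 in DESeq2, 10 at an unadjusted p under 0.05, 0 adjusted over the list alone, adjusted p = 0.00913). Its call ended without scrambled 0 h library 2 (0 members, adjusted p = 0.0884). The ribosome count was 11 without scrambled 0 h library 1, 5 without NAA50 0 h library 1, 1 without scrambled 12 h library 2 or NAA50 0 h library 2, and 0 without scrambled 0 h library 3, scrambled 12 h library 1, NAA50 0 h library 3, or NAA50 12 h library 1 or 2.

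Lists without a camera call at 12 h also held members that responded. In the auxin list 4 members were higher and 9 lower of 22 (6 and 10 adjusted over the list alone, camera adjusted p = 0.332). The higher ones included the auxin efflux carriers PIN7 (2.78 ± 0.25) and PIN3 (1.68 ± 0.17) and the repressor IAA29 (3.78 ± 0.53). In the circadian clock list 2 were higher and 4 lower of 22 (2 and 4 adjusted over the list alone, camera adjusted p = 0.455), with RVE1 (-1.59 ± 0.22) and LHY (-0.61 ± 0.14) lower and ELF3 higher (1.05 ± 0.24). In the heat shock and cytosolic protein folding list 3 of 21 were lower (3 adjusted over the list alone, camera adjusted p = 0.156). They were GolS1, a galactinol synthase at 10.8 CPM in the NAA50 line against 60.1 in the scrambled line, the chaperone HSC70-1 (-0.72 ± 0.18) and HSFB2A (-0.85 ± 0.23). Among phloem and bundle markers 1 of 8 was higher, the sucrose transporter SUC2 (1.44 ± 0.24), and 3 were lower, among them the sulfate transporter SULTR2;1 (-2.79 ± 0.33) and the sugar exporter SWEET12 (-4.77 ± 0.96), with the same counts adjusted over the list alone (camera adjusted p = 0.561).

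BAG7, a co-chaperone of the endoplasmic reticulum (ER), rose in the NAA50 line from 89.8 ± 8.03 CPM at 0 h to 251 ± 20.4 at 12 h and fell in the scrambled line from 89.3 ± 8.61 to 53.7 ± 3.65 (response 2.22 ± 0.17, adjusted p = 7.41e-07). IRE1A, a sensor of unfolded proteins, had a response of 1.26 ± 0.23 and PDIL1-4, a protein disulfide isomerase, one of 0.85 ± 0.14. The cyclin genes CYCD3;3 (3.71 ± 0.34) and CYCD3;1 (3.03 ± 0.64) had positive responses, and PRL, a replication licensing factor, a negative one (-1.78 ± 0.41). In the ER list 4 of 32 members were higher and 2 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.838), and in the cell division list 2 and 2 of 17 (the same, 0.949). With 1 library left out 0 to 2 were lower in the ER list and 1 to 2 in the cell division list. Of 5 xylem markers 1 was higher, the protease XCP1 (2.01 ± 0.41; 1 adjusted over the list alone, camera adjusted p = 0.332). In the abscisic acid, cell division and ER lists the median and the mean or the test differed in sign. The ethylene, jasmonate and pattern-triggered immunity lists were not called, but camera called them without scrambled 0 h library 3 (adjusted p = 0.0229), and the jasmonate list also without NAA50 0 h library 3 (0.0333).

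In the pattern-triggered immunity list 1 of 24 members was higher at 12 h and 3 were lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.274). BAK1, a co-receptor of pattern recognition, was higher (0.80 ± 0.22), and the immune kinase FRK1 (-2.14 ± 0.68) and PROPEP2, which encodes a danger peptide precursor (-4.65 ± 1.49), were lower. The FRK1 and PROPEP2 calls each ended without any 1 of 8 of the 12 libraries, and PROPEP2 was at -8.31 without scrambled 0 h library 3. The lower members numbered 6 without scrambled 0 h library 3, 3 without NAA50 12 h library 3 and 0 to 2 without each of the others, and 2 were higher without NAA50 0 h library 1. In the jasmonate list 1 of 22 was higher, the repressor JAZ10 (3.86 ± 0.95), and 2 were lower (the same adjusted over the list alone, camera adjusted p = 0.332). They were ST2A, a sulfotransferase of hydroxyjasmonate (-3.11 ± 0.85), and TIFY7, listed as JAZ9 (-1.54 ± 0.46). The JAZ10 call ended without scrambled 0 h library 3 (2.35, adjusted p = 0.183) and that of TIFY7 without any 1 of 5 of the 12 libraries. The jasmonate counts were 0 higher and 5 lower without scrambled 0 h library 3, 2 higher without NAA50 0 h library 1, and 1 lower without any 1 of the 5 libraries that ended the TIFY7 call. Of 5 epidermis markers 1 was higher, the wax gene CER1 (2.54 ± 0.89), and 2 were lower, the regulators TRY (-2.15 ± 0.43) and ATML1 (-1.08 ± 0.30), with the same counts adjusted over the list alone (camera adjusted p = 0.416). The CER1 call ended without any 1 of 9 of the 12 libraries, with the sample number as a block and with only the 4 groups compared in the fit.

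At 12 h other lists had lower members and 0 higher. They were 5 of 14 cell wall loosening genes, with EXPA1 (-1.78 ± 0.48), TCH4 (-2.31 ± 0.62) and XTH9 (-1.74 ± 0.52), and 4 of 15 senescence genes, with XTH24 (-3.63 ± 0.79), SAG13 (-2.86 ± 0.78) and SAG20 (-1.105 ± 0.23). The counts were the same adjusted over the list alone (camera adjusted p = 0.274 and 0.561). In the ethylene list 3 of 14 were lower (3 adjusted over the list alone, camera adjusted p = 0.156), among them ACS2, an enzyme of ethylene synthesis (-2.97 ± 0.93), and the chitinase HCHIB (-1.69 ± 0.53), overlapped over 85.4% of its length by another gene. Of 9 guard cell markers 2 were lower (2 adjusted over the list alone, camera adjusted p = 0.455), KAT1 (-0.83 ± 0.26) and OZS1 (-1.21 ± 0.40). Of 27 abscisic acid genes RD26 (-1.19 ± 0.35) and RD20 (-3.34 ± 1.098) were lower (0 adjusted over the list alone, camera adjusted p = 0.949), and of 5 acetyltransferase subunits AT5G13780 (-0.37 ± 0.12; 1 adjusted over the list alone, camera adjusted p = 0.455). Calls ended without any 1 of 4 of the 12 libraries for RD26, 5 for ACS2, 6 for XTH9, 7 for HCHIB, KAT1 and OZS1, 8 for RD20 and 9 for AT5G13780. With library-size scaling the calls of KAT1, OZS1 and AT5G13780 ended, with the sample number as a block, DESeq2 or only the 4 groups in the fit that of OZS1, with DESeq2 size factors that of AT5G13780 and with only the 4 groups that of ACS2. With 1 library left out the lower members numbered 2 to 5 in the cell wall, 0 to 5 in the ethylene, 0 to 2 in the guard cell and 0 to 4 in the abscisic acid list, where up to 5 were higher, and up to 1 was higher in the cell wall and senescence lists.

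By edgeR 4586 genes had a knockdown response at 12 h, 2161 positive and 2425 negative. Of the positive ones 1533 rose in the NAA50 line and 881 fell in the scrambled line, with 305 in both sets. Of the negative ones 1329 fell in the NAA50 line and 1255 rose in the scrambled line, with 223 in both. The p-values measure differences against the spread among samples of pooled plants, and as each amiRNA is represented by 1 line, an effect of the insertion that needs induction stays within the response. At 12 and 24 h there were no plants without dexamethasone.

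At 24 h NAA50 had a knockdown response of -2.12 ± 0.24 (adjusted p = 2.21e-05). CYS2 was at 2522 ± 497 CPM in the NAA50 line against 1.71 ± 0.870 in the scrambled line (1468-fold), PME5 at 52.5 ± 20.8 against 0.313 ± 0.159 (166-fold) and UMAMIT8, of the same transporter family as UMAMIT17, at 63.0 ± 7.92 against 0.144 ± 0.0472 (429-fold). PEI1 was at 24.4 ± 6.12 CPM against 2 counts in the scrambled libraries, 413-fold higher with a counting interval of 114 to 3418. AT3G59710 was at 7.11 ± 1.14 CPM and CYP702A2, a cytochrome P450, at 9.67, both at 0 in the scrambled libraries at 24 h and at least 81.1-fold and 109-fold higher. The CYP702A2 response of 9.89 was 7.92 without scrambled 0 h library 3, where its call ended. Intervals and these floors of 3 counts over a group cover counting error only.

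Negative responses at 24 h included AT1G13650, at 0.172 ± 0.0681 CPM in the NAA50 line against 15.8 ± 10.3 in the scrambled line (91.5-fold), AT5G02760 at 0.238 ± 0.246 against 13.9 ± 7.15 (53.8-fold) and AT4G16563 at 1.04 ± 1.04 against 28.3 ± 11.3 (25.2-fold). MYB50, a MYB transcription factor, had a response of -4.82 ± 0.89. AT3G46280 was at 1.89 ± 2.18 against 11.9 ± 4.95, a 5.56-fold difference between the lines at 24 h that is not its response. AT1G14250 had a response of -5.59 ± 1.91 (adjusted p = 0.0377). Its call ended without scrambled 0 h library 1 (-5.16, adjusted p = 0.0670) or 3 (-5.47, 0.0606), scrambled 24 h library 3 (-4.23, 0.187), NAA50 0 h library 2 (-3.16, 0.119) or NAA50 24 h library 1 (-5.10, 0.0823), 2 (-5.55, 0.0805) or 3 (-6.59, 0.0555).

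In the salicylic acid and systemic immunity list 14 of 27 members had a lower response at 24 h (17 lower adjusted over the list alone, median -1.91, camera adjusted p = 7.93e-06, adjusted p = 0.964 with an estimated correlation). WRKY70, a transcription factor of salicylic acid signalling, was at 285 ± 92.1 CPM in the NAA50 line against 844 ± 257 in the scrambled line (response -1.92 ± 0.42), and WRKY38 at 5.17 ± 3.55 against 35.6 ± 19.5 (response -3.97 ± 0.88). PCC1 was at 96.4 ± 53.5 against 659.7 ± 52.5 CPM (response -2.96 ± 0.64). The count of this list was 22 without scrambled 0 h library 3, 9 without scrambled 24 h library 2 or NAA50 0 h library 3, and 8 without NAA50 24 h library 2. In the xylem list 5 of 5 markers had a higher response (5 adjusted over the list alone, median 2.35, camera adjusted p = 7.45e-04, adjusted p = 0.964 with an estimated correlation). IRX1, a cellulose synthase of secondary walls, rose from 4.31 ± 0.885 CPM at 0 h to 16.9 ± 1.88 in the NAA50 line and was at 3.04 ± 0.908 in the scrambled line. XCP1 (2.84 ± 0.40) and the second cellulose synthase CESA4 (2.33 ± 0.37) had positive responses too.

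No other list had a camera call at 24 h with all libraries, but members of most lists responded. In the auxin list 5 of 22 were higher and 7 lower (6 and 8 adjusted over the list alone, median -1.10, or -1.16 with the member at the counting floor set to its bound, camera adjusted p = 0.773), with IAA29 at 4.78 ± 0.55 and PIN7 at 2.58 ± 0.26. The cold and drought genes COR47 (2137 ± 581 against 127 ± 24.4 CPM, response 2.80 ± 0.67), ERD10 (2.66 ± 0.67) and RD22 (1.26 ± 0.30) had positive responses. The abscisic acid and drought list missed the call (adjusted p = 0.0829) but was called without scrambled 0 h library 2 (0.0380), scrambled 24 h library 2 (0.0276) or NAA50 0 h library 3 (9.90e-06) and with library-size scaling (0.0336). Positive too were the clock genes GI (1.35 ± 0.20), GRP7 (2.07 ± 0.33) and ELF3 (1.52 ± 0.25), and BAG7 (298 ± 45.3 against 64.6 ± 3.74 CPM), IRE1A (1.22 ± 0.23), CYCD3;3 (3.70 ± 0.34) and SUC2 (1.63 ± 0.24). CYP94B3, which oxidises the active jasmonate (5.04 ± 1.27), the ethylene response factor ORA59 (3.39 ± 0.88), ACD2 of chlorophyll breakdown (1.24 ± 0.24) and the wax gene KCS6 (1.05 ± 0.29) were positive as well. JAZ10 had a response of 3.58 ± 0.92 at 24 h, and its call ended without scrambled 0 h library 3 (2.07, adjusted p = 0.216).

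Further members of the lists passed at 24 h, with camera adjusted p from 0.247 to 0.939. In the jasmonate list 3 of 22 were higher and 1 lower, JAR1, which makes the active jasmonate (-0.76 ± 0.18), and in the ethylene list 2 of 14 were higher and 1 lower, with ACS6 (1.35 ± 0.47) and HCHIB (-1.42 ± 0.50). In the senescence list 1 of 15 was higher and 3 lower, with XTH24 (-2.77 ± 0.77) and SEN1 (-3.01 ± 0.90), and in the camalexin list 3 of 16 were lower, CYP79B3 (-1.99 ± 0.59), CYP71A12 (-2.72 ± 0.84) and MYB34 (-1.54 ± 0.48). In the cell wall loosening list 2 of 14 were higher, with the expansin EXPA4 (1.09 ± 0.30), and 3 lower. In the cell division list 3 of 17 were higher, CYCD3;3, CYCD3;1 (2.16 ± 0.64) and the Aurora kinase AUR1 (1.90 ± 0.51). In the heat shock list 2 of 21 were higher, AT-HSFB2B (1.18 ± 0.33) and DREB2A (2.21 ± 0.67), and GolS1 lower. In the oxidative stress list 1 of 22 was higher, the zinc finger factor RHL41 (1.42 ± 0.32), and 5 lower. Of 9 guard cell markers 2 were higher, with the myrosinase TGG1 (1.13 ± 0.35), and 2 lower. The phloem list had 2 of 8 higher and 3 lower, with HA3 at -0.80 ± 0.14, the pattern-triggered immunity list 1 of 24 higher and 5 lower, and the epidermis list 1 of 5 higher and 1 lower. Adjusted over the list alone the counts were 1 and 0 for ethylene, 2 and 4 for senescence, 2 and 3 for guard cells and 2 and 2 for epidermis, and the same for the others.

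Many of these counts at 24 h moved with 1 library left out. The higher and lower members ran from 2 to 5 and 1 to 6 in the jasmonate list, 1 to 4 and 0 to 2 in the ethylene list, 1 to 3 and 1 to 4 in the senescence list, and 0 to 3 and 3 to 6 in the pattern-triggered immunity list. For guard cells they ran from 0 to 2 and 2 to 3, for heat shock from 1 to 4 and 1 to 2 and for epidermis from 1 to 2 each. The higher members ran from 1 to 2 in the cell wall and 2 to 4 in the phloem list. The lower members of the camalexin and oxidative stress lists ran from 1 to 5 and 2 to 7. The calls of ACS6 and HCHIB ended without any 1 of 8 and 9 of the 12 libraries, those of CYP71A12 and MYB34 without any 1 of 5 and 4, and that of CYCD3;1 without any 1 of 3. The TGG1 call ended without scrambled 0 h library 3 (adjusted p = 0.0560), scrambled 24 h library 3 (0.0563) or NAA50 24 h library 2 (0.0822), the DREB2A call without scrambled 0 h library 3 (0.0893) and the SEN1 call without NAA50 24 h library 2 (0.0540). With only the 4 groups in the fit the calls of CYP79B3, MYB34, ACS6, HCHIB and SEN1 ended, as did that of ACS6 with library-size scaling and that of HCHIB with DESeq2.

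Negative responses at 24 h in the lists included the immune kinase FRK1 (-3.16 ± 0.68), WRKY18 (-2.02 ± 0.55) and the chitin receptor CERK1 (-0.77 ± 0.22), GSTU10 (-3.57 ± 0.59) and OPR1 (-1.32 ± 0.26). The photosynthesis list (median -0.30, adjusted p = 0.229) was called as lower without scrambled 0 h library 2 (0.0123), scrambled 24 h library 2 (3.14e-04), NAA50 0 h library 3 (0.0353) or NAA50 24 h library 2 (0.0229). The anion channel OZS1 (-2.05 ± 0.42), overlapped over 38.1% of its length by another gene, and the potassium channel KAT1 (-1.08 ± 0.26) of guard cells, SULTR2;1 (-2.07 ± 0.32), the wall enzymes XTH9 (-2.87 ± 0.56) and XTH33 (-4.78 ± 1.12), GolS1 (-1.97 ± 0.34) and TRY (-2.60 ± 0.50) were negative too. The list of N-terminal acetyltransferase subunits other than NAA50 left out NAA15, NAA30 and NAA35 for their symbols in the annotation. Of its 5 members 1 had a lower response (2 adjusted over the list alone, camera adjusted p = 0.247), and that count was 2 without scrambled 24 h library 3 or NAA50 24 h library 3. The lower member was AT5G13780, listed as NAA10, the catalytic partner of the NatA complex (-0.45 ± 0.12). In the cell wall loosening, ethylene, guard cell, jasmonate and phloem lists the median, the mean or the test differed in sign, and with library size in place of TMM scaling the medians of the clock and phloem lists changed sign. By edgeR 5457 genes had a knockdown response at 24 h, 2693 positive and 2764 negative. Of the positive ones 1867 rose in the NAA50 line and 1183 fell in the scrambled line, and of the negative ones 1444 fell in the NAA50 line and 1506 rose in the scrambled line.

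**Figure D3:**
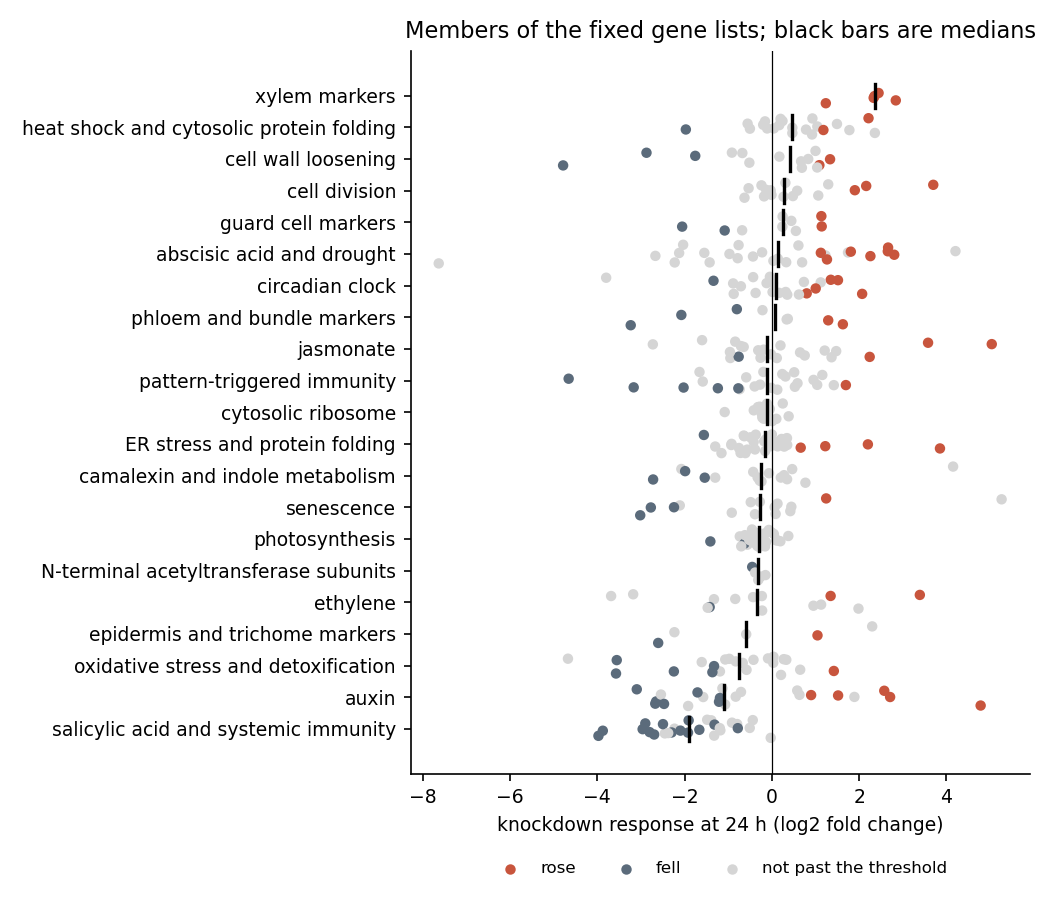
Log2 knockdown response at 24 h of the tested members of 21 gene lists, with the log2 response on the x axis and the lists on the y axis. Each point is 1 gene, coloured by whether it passed the test, and the bar is the list's median. The xylem markers (median 2.35) and the salicylic acid and systemic immunity list (median -1.91) lie farthest from 0.

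The direct difference between the lines at 12 h asks how their leaves differed at that time, with any difference present at 0 h included. NAA50 was at 24.5% of the scrambled level. Genes at 0 counts in the scrambled libraries at 12 h included AT5G10120 (at least 533-fold higher), AT3G23470 (at least 147-fold) and NIC3, a nicotinamidase (at least 109-fold), beside PEI1. They also included AT1G14220, at 11.2 ± 2.72 CPM in the NAA50 line (at least 120-fold). BRS1, a serine carboxypeptidase, was lower at 0.134 ± 0.125 against 18.7 ± 7.55 CPM (139.5-fold), ABCB15, an ABC transporter, at 0.190 ± 0.265 against 8.03 ± 0.760 (43.2-fold) and AT1G13650 at 0.633 ± 0.336 against 29.5 ± 14.5 (45.8-fold). HMA2 (-6.97 ± 0.89), UMAMIT17 (-6.06 ± 0.99) and AT5G05250 (-5.93 ± 0.54) were lower as well.

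In the photosynthesis list 39 of 41 members were lower in the NAA50 line at 12 h (41 adjusted over the list alone, median -0.97, camera adjusted p = 6.66e-11, adjusted p = 0.833 with an estimated correlation). RBCS2B was at 430.3 ± 50.4 CPM against 2300.5 ± 328 and PSBO2, of the oxygen-evolving complex, at 706 ± 60.7 against 1348 ± 72.2. In the cytosolic ribosome list 11 of 25 were lower and 1 higher (the same adjusted over the list alone, median -0.35, camera adjusted p = 0.0112, adjusted p = 0.833 with an estimated correlation), with RP1 at -0.57 ± 0.12, RPSAb at -1.54 ± 0.31 and SAG24 higher at 0.93 ± 0.21. That call ended with library-size scaling (3 lower, 1 higher, adjusted p = 0.0535), and the count of lower members was 7 without scrambled 12 h library 1 or NAA50 12 h library 1.

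Other members of the lists differed at 12 h without a camera call. In the auxin list 13 of 22 were lower and 5 higher (15 and 5 adjusted over the list alone, camera adjusted p = 0.159, and 0.0448 with library-size scaling). In the guard cell list 3 of 9 were lower (3 adjusted over the list alone), among them MYB60 (-0.84 ± 0.18). In the ethylene list 4 of 14 were lower and 1 higher (the same adjusted over the list alone), with PDF1.2b at -7.85 ± 1.89, ERF104 at -1.03 ± 0.28 and EBF2 at 0.82 ± 0.20. In the cell wall loosening list EXPA1 (-2.40 ± 0.35), EXPA11 (-1.85 ± 0.27) and EXPA8 (-2.46 ± 0.41) were lower. That list missed the call (adjusted p = 0.0639) but was called without scrambled 12 h library 1 (0.0482) or 3 (0.0326), without NAA50 12 h library 1 (0.0408) or 2 (0.0316), and with library-size scaling (0.0161). Among the senescence genes 5 of 15 were higher and 2 lower (6 and 2 adjusted over the list alone), with the sugar transporter SAG29 at 158 ± 9.91 against 0.467 ± 0.0946 CPM, WRKY6 at 1.57 ± 0.27 and AT4G11910, listed as NYE2, at 2.69 ± 0.37. In the abscisic acid and drought list 7 of 27 were higher (5 adjusted over the list alone), among them the phosphatases ABI2 (2.05 ± 0.37) and HAI2 (3.10 ± 0.68). That list was called without scrambled 12 h library 1 (adjusted p = 0.0413) or NAA50 12 h library 2 (0.0129). JAZ10 was at 97.3 ± 8.38 against 2.29 ± 1.02 CPM (change 5.40 ± 0.62), and the jasmonate list had 2 of 22 higher and 1 lower, TIFY7 (-1.16 ± 0.33), with the same counts adjusted over the list alone. Of 5 epidermis markers CER1 was higher (3.27 ± 0.68) and TRY (-2.34 ± 0.29) and ATML1 (-1.34 ± 0.22) lower (the same adjusted over the list alone, camera adjusted p = 0.367). BAG7 (2.23 ± 0.13), PIN7 (2.21 ± 0.18), CYCD3;3 (3.36 ± 0.24), BIK1, an immune kinase (1.19 ± 0.23), and UGT74E2, an auxin glucosyltransferase (4.32 ± 0.92), were higher, and SULTR2;1 (-2.78 ± 0.24) and CYP81F2, of indole glucosinolate metabolism (-1.91 ± 0.40), were lower.

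Some list counts at 12 h moved with single libraries or with the scaling. In the ER stress list 6 of 32 were higher and 2 lower (4 and 2 adjusted over the list alone). The counts were 4 and 1 without NAA50 12 h library 1, 5 and 0 without NAA50 12 h library 2, and 6 and 1 without scrambled 12 h library 3. In the cell division list 9 of 17 were lower and 2 higher (the same adjusted over the list alone), and 5 were lower without scrambled 12 h library 2, NAA50 12 h library 1 or NAA50 12 h library 3. In the pattern-triggered immunity list 2 of 24 were higher and 4 lower (the same adjusted over the list alone), and 2 were lower without scrambled 12 h library 1. The salicylic acid and systemic immunity list missed the call (median -0.81, adjusted p = 0.159) but was called as lower without scrambled 12 h library 1 (0.0323). With library-size scaling the medians of the camalexin, clock, acetyltransferase and pattern-triggered immunity lists changed from -0.08, -0.09, -0.15 and -0.05 to 0.09, 0.08, 0.02 and 0.12. By edgeR 8484 genes differed at 12 h, 4018 higher and 4466 lower in the NAA50 line. The higher share was 47.4%, and 63.8% with library-size scaling, which moved the median of all genes by 0.169.

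At 24 h the direct difference showed CYS2 at 10.53 ± 0.63 and several genes at 0 in all 3 scrambled libraries. These were CYP702A3, a cytochrome P450 (at least 354-fold higher, 31.6 ± 7.59 CPM), GLIP2, a GDSL-type lipase (at least 298-fold), AT2G03740 (at least 207-fold), NIC3 (at least 147-fold) and AT1G05577 (at least 139.9-fold). Lower were AT1G13650 (-6.41 ± 0.94), AT5G02760 (-5.68 ± 0.49), BRS1 (56.2-fold), XTH33 (32.5-fold) and BGLU47, of the beta-glucosidase family (29.5-fold). AT2G14247 had 2 counts in the NAA50 libraries, 83.2-fold lower with a counting interval of 22.7 to 693, and its change of -6.06 ± 1.63 became -2.23 without scrambled 24 h library 3 (adjusted p = 0.237).

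The abscisic acid and drought list was higher in the NAA50 line at 24 h, with 20 of 27 members higher (22 higher adjusted over the list alone, median 2.59, camera adjusted p = 1.94e-05, adjusted p = 0.893 with an estimated correlation, as for each list called at 24 h). The protective proteins COR47 and ERD10 were at 2137 ± 581 and 2655 ± 783 CPM against 127 ± 24.4 and 179 ± 25.9, and ABI2 was at 151 ± 21.3 against 25.1 ± 5.49. The 5 xylem markers were all higher (5 adjusted over the list alone, median 2.22, camera adjusted p = 0.00130), with XCP1 at 34.6 against 5.35 CPM. In the photosynthesis list 31 of 41 were lower (33 adjusted over the list alone, median -0.72, camera adjusted p = 3.19e-06), and 15, 17 and 20 without scrambled 24 h library 3, NAA50 24 h library 1 and NAA50 24 h library 3. In the salicylic acid and systemic immunity list 14 of 27 were lower (14 adjusted over the list alone, median -0.78, camera adjusted p = 0.00542), and 9 without NAA50 24 h library 2. PCC1 (-2.77 ± 0.48), WRKY70 (-1.57 ± 0.30) and NIMIN-2, an NPR1-binding protein (-2.47 ± 0.56), were among them.

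Without a camera call at 24 h, 8 of 22 jasmonate genes were higher and 1 lower (7 and 1 adjusted over the list alone), with JAZ10 at 127 ± 26.9 against 3.60 ± 2.17 CPM, JAZ1 at 2.91 ± 0.47 and CYP94B3 at 5.48 ± 0.93. Camera called the jasmonate list without scrambled 24 h library 3 (adjusted p = 0.0220). Of the senescence genes 8 of 15 were higher and 2 lower (the same adjusted over the list alone), with SAG29 at 9.20 ± 0.64 and NYE1, which starts chlorophyll breakdown, at 0.76 ± 0.11. In the camalexin list 6 of 16 were higher and 2 lower (the same adjusted over the list alone), with MYB122 (5.89 ± 0.87) and TSB1, a tryptophan synthase (0.73 ± 0.12), higher and MYB34 lower (-1.85 ± 0.38). Cell wall loosening genes were lower in 6 and higher in 2 of 14 cases (the same adjusted over the list alone), and epidermis markers lower in 3 and higher in 2 of 5 (the same), with EXPA4 (1.38 ± 0.21), CER1 (3.02 ± 0.65) and KCS6 (1.13 ± 0.21) among the higher ones. Of 9 guard cell markers 2 were higher, with CYP86A2, overlapped over 32.8% of its length by another gene, at 0.97 ± 0.26, and 2 lower (the same). Ribosome genes were lower in 1 and higher in 1 of 25 cases (the same), and auxin genes lower in 11 and higher in 6 of 22 (13 and 6 adjusted over the list alone), among them SHY2 (-3.69 ± 0.37), which another gene overlaps over 41.5% of its length. NAC103, a factor of the ER stress response (4.09 ± 0.49), the oxidase RBOHD (1.41 ± 0.27), the receptor EFR (0.74 ± 0.17), DREB2A (3.29 ± 0.46) and GI (1.42 ± 0.14) were higher. The proton pump HA3 (-0.69 ± 0.10), KAT1 (-1.14 ± 0.18) and AT5G58450, listed as NAA25 (-0.48 ± 0.10), were lower. In the cell division and guard cell lists the median and the mean or the test differed in sign. By edgeR 8794 genes differed at 24 h, 4378 higher and 4416 lower in the NAA50 line.

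**Figure D4:**
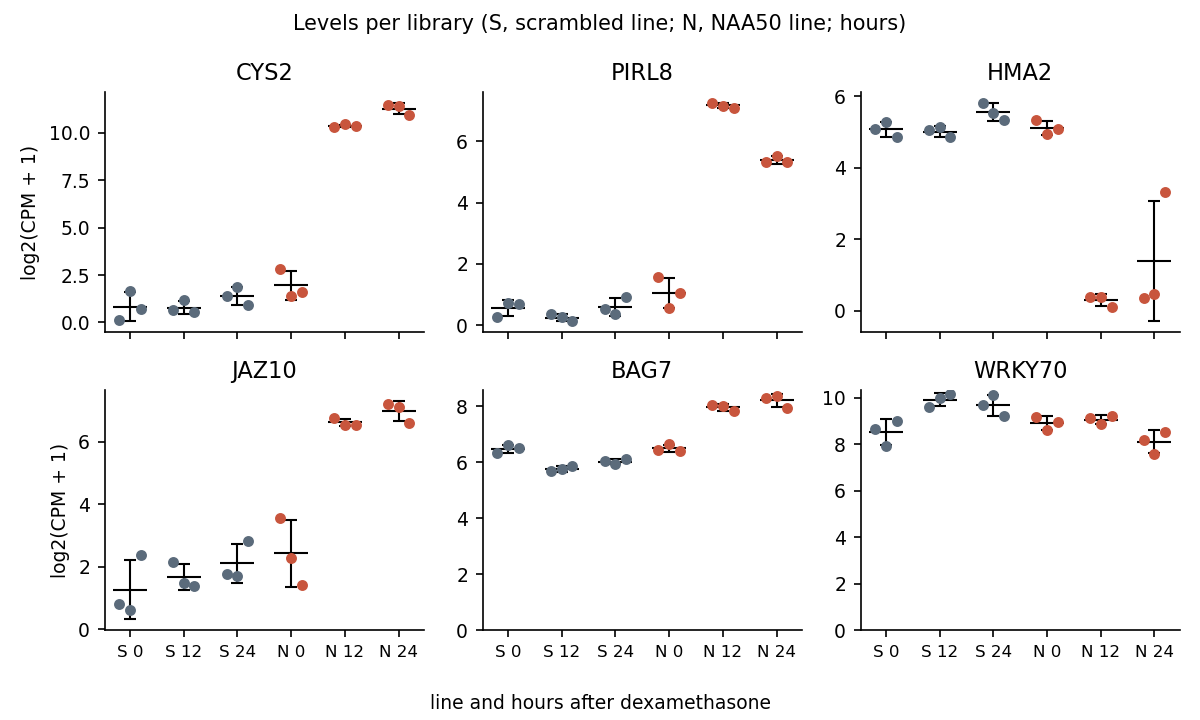
Levels of 6 named genes as log2(CPM + 1) on the y axis by line (S, scrambled; N, NAA50 line) and hours after dexamethasone on the x axis, with 1 point per library and bars for the mean ± SD of 3 libraries. CYS2, PIRL8, JAZ10 and BAG7 lie higher and HMA2 and WRKY70 lower in the NAA50 line than in the scrambled line at 12 and 24 h.

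The differences between the lines at 12 and 24 h shared 5448 genes in the same direction, 64.2% of those called at 12 h, with 2711 higher at both times (959 for independent sets) and 2737 lower at both (1075 for independent sets). CYS2, PEI1, BAG7 and PIN7 were higher and NAA50, HMA2 and SULTR2;1 lower at both times. Among the NAA50 libraries at 24 h, library 3 had higher levels than libraries 1 and 2 of HMA2 (8.95 against 0.295 and 0.378 CPM), UMAMIT17 (9.69 against 0.0983 and 0.0946), XTH24 (240.1 against 37.9 and 27.1) and NAA50 (4.62 against 2.36 and 3.31). Without it the responses at 24 h of XTH24 (-2.77) and CYP79B3 (-1.99) were -4.42 and -3.15. Another 125 genes were called in opposite directions, among them RHL41, a zinc finger protein of oxidative stress (-1.19 at 12 h and 1.23 at 24 h). The changes at both times correlated across 18344 genes (r = 0.808), and genes are not independent replicates. The knockdown responses at both times shared 2864 genes (r = 0.815), 1469 positive and 1395 negative, with 17 in opposite directions. Both responses use the same 0 h libraries, which alone gave r = 0.511 in 10 simulations without a response. The covariance in these simulations was 0.0921, against 1.17 in the data, and 0 genes were called at both times, against 2864.

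Genes whose line difference changed between 12 and 24 h were tested as the difference at 24 h minus that at 12 h. RHA2B, a ubiquitin ligase of abscisic acid signalling, went from 1.66 ± 0.647 CPM in the NAA50 line at 12 h to 16.3 ± 5.83 at 24 h and from 2.08 ± 0.0849 to 0.401 ± 0.154 in the scrambled line (5.61 ± 0.51). DDF1, a dehydration-responsive transcription factor, had a difference of 5.09 ± 0.96. AT1G24130 had one of 4.92 ± 1.27, with 0 counts in the scrambled line at 24 h and at least a 33.3-fold higher level in the NAA50 line. Its level fell in both lines, from 6.97 CPM at 12 h to 2.96 at 24 h in the NAA50 line and from 0.777 CPM to 0 in the scrambled line. The size of its fitted difference thus depends on the 0 counts in the scrambled line. AGP17, an arabinogalactan protein (-3.52 ± 0.56), PIRL8 (-3.31 ± 0.71) and AT5G02760 (-3.28 ± 0.73) had negative differences. The 5 xylem markers had a median of 2.04, with 3 of 5 higher (5 adjusted over the list alone, camera adjusted p = 3.01e-04, adjusted p = 0.702 with an estimated correlation). By edgeR 1242 genes passed, 813 with a positive and 429 with a negative difference. The share of positive ones was 65.5%, and with library-size scaling the majority turned to 35.3%, the median of all genes moving by -0.171. The count ranged from 603 to 1841 with 1 library left out, and it was 603, 777, 633 and 723 without scrambled 12 h library 1 and 2 and scrambled 24 h library 1 and 2, 753, 802 and 705 without NAA50 12 h library 1, 2 and 3, and 820.0 and 672 without NAA50 24 h library 1 and 2. The call of AT1G24130 ended without 9 of the 12 libraries (4.70 to 4.97, adjusted p from 0.0565 to 0.0861) and with the sample number as a block (4.92, adjusted p = 0.0503), and that of PIRL8 without scrambled 24 h library 3 (-2.72, adjusted p = 0.0545).

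The time courses show how each line changed after the spray. In the scrambled line at 12 h, AT2G27420 (72.7-fold), LSU3, which responds to sulfur shortage (63.2-fold), and AT4G34550 (63.7-fold) rose, and AT1G50040 (change -5.30 ± 0.86), AT5G02170 (40.2-fold) and PORB, a protochlorophyllide reductase (26.9-fold), fell. Of the heat shock list 14 of 21 rose (18 adjusted over the list alone, median 1.53, camera adjusted p = 2.92e-06, adjusted p = 0.692 with an estimated correlation). In the NAA50 line 12 of 21 rose at 12 h (13 adjusted over the list alone, median 1.26, camera adjusted p = 0.0111, adjusted p = 0.947 with an estimated correlation). At 24 h in the scrambled line HAI1, a phosphatase of abscisic acid signalling, rose (45.9-fold), HIPP22 rose 81.5-fold from 2 counts (counting interval 22.2 to 678), and PORA, a second protochlorophyllide reductase, fell 86.3-fold to 3 counts (29.2 to 421). PORB fell too (22.0-fold), as did ORA47, a jasmonate regulator (22.3-fold), and GSTU3 rose by 5.40 ± 0.90, or by 8.20 without scrambled 0 h library 3.

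In the NAA50 line at 12 h PEI1 (at least 384-fold), AT1G14220 (at least 129-fold) and AT2G43730 (at least 88.9-fold) rose from 0 counts at 0 h. HMA2 fell 142-fold, the cyclin gene CYCP4;1 132-fold to 3 counts (counting interval 44.8 to 643) and AT5G48490 263-fold to 1 count (46.8 to 10435). At 24 h PEI1 (at least 277-fold) and GLIP2 (at least 300.3-fold) rose from 0 counts and AT3G23470 rose 1715-fold from 1 count (307 to 67792). AT1G13650 fell 393-fold, EXPB1, an expansin, 102-fold to 2 counts (28.0 to 851) and AT5G48490 at least 79.4-fold to 0 counts. Photosynthesis genes fell in both lines from 0 to 24 h, 40 of 41 in the scrambled line (median -1.43, camera adjusted p = 3.06e-14, adjusted p = 0.793 with an estimated correlation) and 41 of 41 in the NAA50 line (median -1.66, camera adjusted p = 2.39e-15, adjusted p = 0.803 with an estimated correlation), with the same counts adjusted over the list alone. Salicylic acid and systemic immunity genes rose in the scrambled line in 24 of 27 cases (24 adjusted over the list alone, median 2.099, camera adjusted p = 1.83e-07, adjusted p = 0.793 with an estimated correlation). In the NAA50 line the list had a median of 0.14 (camera adjusted p = 0.646).

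By edgeR 8109 genes changed from 0 to 12 h in the scrambled line (4342 higher, 3767 lower) and 9289 in the NAA50 line (4806 higher, 4483 lower). From 0 to 24 h 9917 changed in the scrambled line (5060 higher, 4857 lower), where library-size scaling moved the median of all genes by 0.125, and 9986 in the NAA50 line (5147 higher, 4839 lower). PORB fell in both lines at 12 h, and 4503 genes changed the same way in both and 528 in opposite ways. At 24 h these counts were 5501 and 651. The changes of the lines correlated across genes with r = 0.472 at 12 h and r = 0.468 at 24 h.

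**Figure D5:**
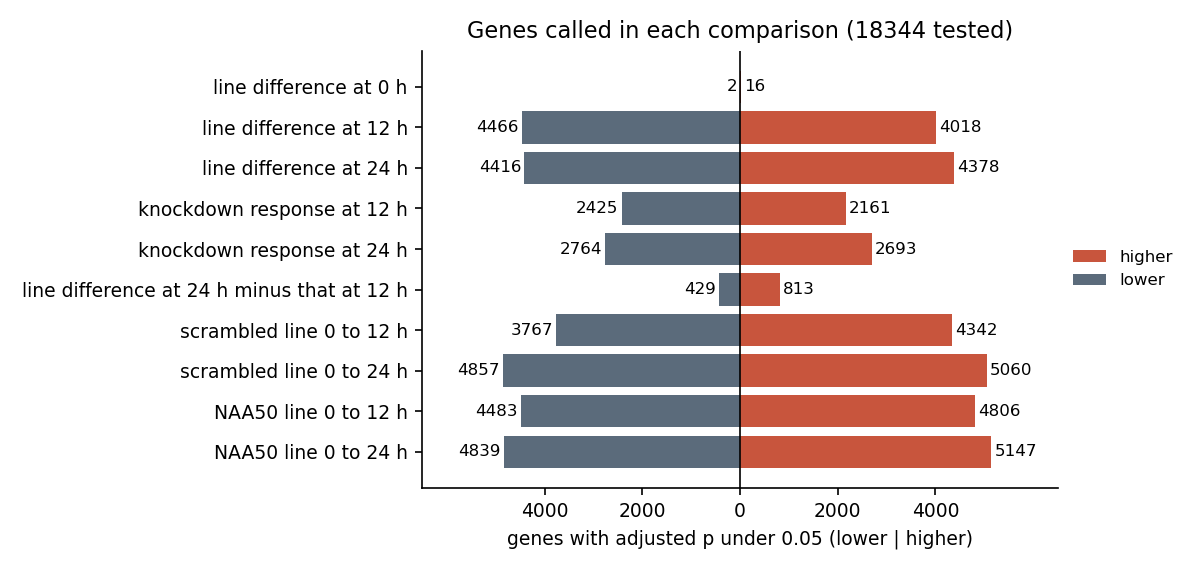
Number of genes called by edgeR on the x axis for each of 10 comparisons on the y axis, with genes higher to the right of 0 and genes lower to the left. The line difference at 0 h has 18 genes and the other 9 comparisons have 1242 to 9986.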

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

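The test with organ marker genes was chosen only after the result it measures was seen, and the rule for calling the TCP targets a set was tightened after their median was seen. The regrouping that exchanges the lines and the grouping of the others by mixing were also chosen after the counts were seen. The results below stand here because a test of the difference between the lines' responses, or between the times, passed.

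A knockdown response was called for 4586 genes at 12 h, among them CYS2 and HMA2. Of the 40 regroupings drawn of 200, 1 gave as many (the real one; the highest other gave 4433). At 24 h 5457 genes were called, and 2 of 40 regroupings gave as many, the other with 6562. For the line difference at 24 h minus that at 12 h, 1242 genes were called and 4 of 40 regroupings gave as many, the highest with 10965. The regroupings with 6562 and 10965 genes exchange the lines at 1 time and keep their libraries together. That regrouping was not drawn for the response at 12 h, where it called 6774 genes. Regroupings that keep the lines apart at a time carry their real difference at that time, a structure of the samples, so they do not measure chance. Those drawn that mix the lines at both times, 37 at 12 h, 27 at 24 h and 33 for the difference between the times, called at most 0, 1 and 0 genes by edgeR, but mixing also widens the spread within each group. Whether chance can be excluded is therefore not settled by these counts.

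The named genes with the largest positive change of the line difference from 12 to 24 h were RHA2B (5.61), DDF1 (5.09) and AT1G24130 (4.92). Those with the largest negative change were AGP17 (-3.52), PIRL8 (-3.31) and AT5G02760 (-3.28). AT1G24130 itself fell in the NAA50 line, from 6.97 CPM at 12 h to 2.96 at 24 h. Its positive change depends on 0 counts in the scrambled line at 24 h. Of the 166 genes named by the rule over all comparisons, 28 differed between the times, 23 of them with a positive change. They include the genes above, which were named because they passed this test. Among all 18344 genes tested, 1242 passed it. The call of AT1G24130 ended without any 1 of 9 of the 12 libraries and with the sample number as a block, and that of PIRL8 without scrambled 24 h library 3 (-2.72, adjusted p = 0.0545). Camera called a positive change for 8 lists. Its median was 2.04 for xylem, 1.305 for ethylene, 1.11 for abscisic acid, 0.76 for heat shock and 0.57 for camalexin. It was 0.37 for the clock, 0.28 for photosynthesis and 0.20 for the ribosome. The photosynthesis list stayed lower in the NAA50 line at 24 h. None of these 8 calls held with an estimated correlation (adjusted p from 0.702 to 0.763). The ribosome call ended with library-size scaling (adjusted p = 0.158) and without scrambled 12 h library 1 (0.0930) or 2 (0.0860), scrambled 24 h library 1 (0.0544) or 2 (0.0904), NAA50 12 h library 1 (0.0559) or NAA50 24 h library 3 (0.214). The camalexin call ended without NAA50 12 h library 2 (0.0549), and the ethylene call without scrambled 24 h library 3 (0.0614). The abscisic acid median was 0.54 without NAA50 24 h library 2 and the clock median 0.20 with library-size scaling, both still called. The photosynthesis call ended without scrambled 12 h library 2 (0.1005), scrambled 24 h library 2 (0.611), NAA50 12 h library 3 (0.201) or NAA50 24 h library 2 (0.207).

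A set of 86 genes was under 1 CPM in the scrambled line at all 3 times and in the NAA50 line at 0 h, and reached 5 CPM or more in the NAA50 line at 12 or 24 h, 41 of them at both, against 1 gene with the mirror pattern. They include PEI1, UMAMIT8, PME5 and CYP702A3. Scaling does not account for the set, since 91 genes met the definition with library-size scaling. Of the markers of root, seed, flower or meristem, 29 of 38 were measured, and 26 of them were under 1 CPM before. Of these 26, 0 reached 5 CPM (highest 1.11 CPM), which argues against RNA of these organs only. Other organs and tissues had no markers in this test, so RNA from them stays open. A candidate explanation is direct activation by a GAL4-based dexamethasone-responsive activator, if the lines carry one. The odds ratio of a GAL4 site (11 bp between CGG and CCG) within 1000 bp upstream was 2.141 (95% interval 0.978 to 4.69). Such a site was found in 7 of 86 genes against 230 of 5788 others (Fisher's exact test, two-sided, p = 0.0859). With 10 and 12 bp between them the odds ratios were 1.392 (0.505 to 3.835) and 1.87 (0.749 to 4.67), so the GAL4 spacing did not stand apart. The scrambled line was sprayed too, and by the definition of the set these genes stayed under 1 CPM there. The lines would therefore have to differ in the activator or its induction, and this explanation stays open. A biological response to loss of NAA50 stays open too, as no test here separates it from an effect of the construct.

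Reads at MIR319a (AT4G23713), a microRNA precursor gene, were at 33.6 ± 4.83 CPM at 12 h and 39.5 ± 13.5 at 24 h in the NAA50 line and at 0.282 to 0.581 CPM in the other 4 groups. The endogenous precursor may have risen, and its TCP targets then fall: their median response at 12 h was -0.5083, past the value of -0.5 set for it, but TCP2 (-0.51), TCP3 (-0.67) and TCP10 (-1.21) were negative and TCP4 (0.65) and TCP24 (0.96) positive, so it decides nothing. The reads could also come from the amiRNA precursor of the transgene if it was built on this locus, which the labels do not state. The scrambled line also carries an amiRNA and was at 0.376 ± 0.110 and 0.346 ± 0.0704 CPM, so the lines would have to differ in precursor or in induction, and no value here shows whether the scrambled amiRNA was induced. The other 23 measured microRNA genes had a median of 0.2453, with 1 above 3 (MIR408, 4.84), and as the table holds counts per gene and no reads, these explanations cannot be told apart here.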

How the results depend on the processing

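Of 267 values of the main results under another setting, 235 stayed within 1.5 times the main value or moved less than its spread over left-out libraries, and 32 did not. NAA50 kept its direction and its call at 12 and 24 h under each setting. Of 4297 values of named genes (314 results), 4055 kept direction and call, 242 kept the direction and lost the call, and 0 reversed. Each left-out library ended 3 to 20 of the calls of named genes.

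With a minimum log2 change of 1, which counts fewer genes by construction, the line differences gave 3257 genes at 12 h and 3846 at 24 h, with 2071 shared in the same direction, the knockdown responses 2583 and 3232, the 24 minus 12 h difference 724, the scrambled line 3324 and 4189 and the NAA50 line 4171 and 4811 genes. At 0 h the line difference gave 308 genes with DESeq2, 32 without a filter, 36 with the sample number as a block and 0 with only the 2 groups in the edgeR fit (1708 with an unadjusted p under 0.05), which has fewer samples to estimate the spread. The cause of the others was not tested. With the block the line difference at 12 h gave 8368 genes. The calls of AT1G24130 for the 24 minus 12 h difference (adjusted p = 0.0503) and of OZS1 (0.0511) and CER1 (0.0722) for the response at 12 h ended with it, and no other named call did. The called lists numbered 13 with it too. MAF5 (adjusted p = 0.109) and PGIP2 (0.355) lost their call with only the 2 groups. An estimated correlation gave 0 called lists in place of 13 (0 at an unadjusted p under 0.05 and 16 with fry), as the variance of a list's mean grows with the correlation. The correlations of the time responses were 0.559 at 12 h and 0.550 at 24 h with a mean log2 CPM of 3 or more, a setting that leaves out genes with few counts.

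Leaving out 1 library gave 3 to 354 genes for the line difference at 0 h, 603 to 1841 for the 24 minus 12 h difference, 3524 to 4505 and 4139 to 5735 for the knockdown responses at 12 and 24 h, 7036 to 7835 and 7214 to 8454 for the line differences, and 13 to 18 called lists. The ranges were 6806 to 7854 and 8174 to 10097 in the scrambled line and 7932 to 8693 and 8653 to 9614 in the NAA50 line from 0 to 12 and to 24 h. In simulated data, with changed genes at a mean of 5 CPM or more, the knockdown response at 24 h found 36% of 2-fold increases, and the line difference at 24 h found 80%.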

Other observations

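The test of the clock genes was chosen, and its rule later tightened, only after the result it measures was seen. Clock genes moved in both lines between the harvests. CCA1 and LHY, which peak around dawn, rose in the scrambled line from means of 194 and 143 CPM at 0 h to 737 and 895 at 12 h (n = 3). In the NAA50 line they rose from 177 and 154 to 556 and 634. At 24 h LHY was at 619 ± 34.1 CPM in the scrambled line and 517 ± 23.3 in the NAA50 line, above its level at 0 h in both (the smaller change was 1.74). RVE8 rose in both lines at 12 h, to 152 ± 8.52 and 140.4 ± 8.39 CPM, and GI rose more in the NAA50 line (285 ± 18.7 CPM against 149.9 ± 23.4, difference of the changes 0.85 ± 0.20, adjusted p = 0.00570).

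A shift of 12 h of clock time between these harvests could move dawn and evening genes in opposite directions. The lowest change of CCA1 and LHY from 0 to 12 h over both lines was 1.654, and the median of 6 evening genes was 0.6151 in the scrambled line and 0.06649 in the NAA50 line, so the evening genes did not fall in the median. Of these 6 genes 1 (TOC1) reached 5 CPM in a group, and the clock times of harvest and spray are not given in the sources used here, so the shift stays open. No plants without dexamethasone were sampled at 12 and 24 h, so time of day, dexamethasone and the spray stay confounded within a line.

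Several microRNA precursor genes had other levels in the NAA50 line. MIR408 was at 9.86 ± 3.29 CPM at 12 h and 15.1 ± 1.98 at 24 h against 0.381 ± 0.299 and 0.445 ± 0.494 in the scrambled line, MIR824 at 14.2 ± 6.33 against 1.14 ± 0.351 at 24 h and MIR860 at 42.6 ± 10.4 against 11.8 ± 3.16 at 24 h. MIR167d was at 0.318 ± 0.0794 CPM at 12 h against 6.04 ± 0.970, and MIR825 at 0.295 ± 0.208 against 1.05 ± 0.358. These genes were chosen after their values were seen, and precursor reads do not measure the mature microRNA.

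For the comparisons of 3 against 3 libraries the 10 regroupings cannot give a share under 0.1. The real grouping alone gave the highest count in each, so that 1 of 10 gave as many: 18 genes at 0 h (highest other 6), 8484 and 8794 for the line differences at 12 and 24 h, 8109 and 9917 for the scrambled line and 9289 and 9986 for the NAA50 line (highest other 0 by edgeR in these 6). For the line difference at 12 h these include the 3 other regroupings that, as the real one, part all 3 pairs of same-numbered samples.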
